A study of Mus musculus with 2 samples.

How the data were processed

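The series holds 1 wild-type (WT) and 1 Ints11 knockout (KO) single-cell RNA-seq library of mouse bone marrow cells, strain C57BL/6, sorted for c-Kit, the receptor of stem cell factor. Per the labels, sorting took place 4 days after poly(I:C), a synthetic RNA that induces interferon and thereby the Mx1 promoter, which drives Cre recombinase in the KO mice carrying a floxed Ints11 allele. Per the labels' protocols, each library pooled cells of 2 mice, and nothing in the labels or barcodes used here separates the mice, so each genotype is 1 sample. Libraries were made with the Chromium 3' kit, version 3, a droplet method that primes on poly(A) tails and tags each captured molecule with a unique molecular identifier (UMI). Per the submitters' processing notes, the authors used Cell Ranger and the mouse genome build mm10; the Cell Ranger version and the gene annotation release are not given in the sources used here.

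The matrix that the authors deposited for the WT library gives UMI counts per gene and cell barcode, as whole numbers without normalization, for barcodes that had already passed cell calling. The counts of the KO library were not analysed here. For the KO only the list of called barcodes and the list of features were used, so no expression comparison between genotypes was made. The 31053 features were the same in both libraries. Droplet data of this kind also hold free RNA from other cells and droplets with 2 cells, and 3' capture under-represents transcripts without a poly(A) tail, such as those of most replication-dependent histone genes.

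WT barcodes were kept with at least 1000 detected genes and at most 10% of UMIs from mitochondrial genes, after which doublets called by Scrublet (scanpy 1.11.5, automatic threshold) were removed. Of 9325 barcodes, 628 had too few genes and 782 too high a mitochondrial share, 1044 barcodes failing at least 1 of the criteria (11.2%), and 263 of the remaining 8281 (3.18%) were called doublets. The 8018 cells kept had a median of 19816 UMIs and 3382 genes, and the barcodes left out held 6.36% of all UMIs. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 highly variable genes were chosen, and cells were clustered on 30 principal components with 15 nearest neighbours by the Leiden method at resolution 1.0 (igraph 0.11.9, Python 3.11.15, numpy 2.4.6). All genes of the fixed lists below, mitochondrial, ribosomal protein and histone genes, Xist and Y-linked genes were left out of the clustering genes.

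The 23 clusters were named from marker sets for 17 cell types. A cluster took the type with the highest mean standardized marker level, or the next type if the latter had more markers among the 10 genes with the highest fold over the other cells. It stayed unnamed with fewer than 20 cells, with fewer than 3 markers above the library mean, where another type had more markers among those 10 genes, or where it was far shallower than the library and had none of its own markers among them. Clusters with the same name formed a class, written with the ending "-like". Names rebuilt in this way may differ from the authors' own annotation.

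UMIs were summed over the cells of a class and given as CPM (UMIs per 1e6 UMIs of that class) with exact Poisson 95% intervals. Classes of at least 100 cells were compared with the HSPC-like class (hematopoietic stem and progenitor cells) as ratios of CPM with exact conditional 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals (scipy 1.17.1). With 1 library and cells that are not replicates, no test across samples was possible and no p-value was computed. All intervals cover counting error only, not differences between mice or libraries. Shares of cells with a Kit UMI were also computed after each cell was thinned to 5000 UMIs.

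A total of 16 gene lists was compared: Integrator subunits, cleavage and polyadenylation, polymerase II pausing, Polycomb repressive complex 2 (PRC2), interferon response, S phase, G2/M phase, ribosome biogenesis, p53 targets, heme synthesis, immediate-early genes, cytokine receptors, Hoxa and Hoxb genes, Myc and metabolism, oxidative phosphorylation, and replication-dependent histones. For each list the median log2 ratio (prior of 1 count) over members with at least 20 UMIs in both classes together was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called higher or lower below where its median lay outside the central 95% of the random medians. Members of a list vary together, which random lists do not, so a percentile describes this library and is not a test. Since the median gene itself was shifted in several classes, log2 values of lists and genes are given relative to the median of all tested genes of the same comparison. A member is counted as higher or lower where its counting interval lay on the same side of both an equal CPM and the ratio of the median gene. Where a symbol occurred on more than 1 feature, the feature with most UMIs was used; this concerned Ints5, which shares its locus with an overlapping annotated gene, and Atp5o.

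The genes named are Ints11, its paralog Cpsf3 and Kit; for each list and main comparison at most 2 members with the largest and 2 with the smallest ratio among those whose interval excluded 1, plus the member with the highest level; and the 5 highest and 5 lowest ratios among genes with at least 50 CPM in the higher class that were outside the clustering genes, markers and lists, leaving out predicted genes. The text prints part of this set. The main comparisons were planned for neutrophil progenitor-like, erythroid progenitor-like and megakaryocyte lineage-like cells. The erythroid progenitor-like class was named but held 58 cells, under the minimum of 100, so the monocyte lineage-like class was used in its place. That substitute had been fixed beforehand for a class that could not be named, and its use for a class that was too small was decided afterwards.

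The cell filter, clustering settings, gene lists, markers, the rule for named genes and most alternative settings were fixed before the data were examined. Chosen afterwards were the use of the monocyte lineage-like class as a main comparison, the scoring rule for cluster names, the thinning depth, the rule for repeated symbols, the statement of values relative to the median gene, the macrophage-like cells shown beside Kit, the count of members on the same side of both scalings, random lists without clustering genes, the comparison of Ints11 with the other subunits across alternatives, the simulated unchanged lists, and the patterns weighed in the closing section. Alternatives fixed beforehand were no cell filter, a filter at 2000 genes and 5% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2.0, 4000 highly variable genes, list genes allowed in clustering, clusters and values from separate portions of the UMIs, scaling by the median gene ratio, totals without haemoglobin and the 50 most abundant genes, a mean over cells, and no minimum of UMIs.

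The comparison was tested on counts simulated from the HSPC-like profile at the real class totals, with 200 genes changed in either direction. Intervals excluded an equal level for 81% of 1.5-fold changes in the neutrophil progenitor-like comparison (12074 genes), 71% in the megakaryocyte lineage-like one (11163 genes) and 83% in the monocyte lineage-like one (11786 genes), and for 96%, 96% and 97% of 3-fold changes. Among unchanged genes the intervals excluded an equal level for 4.29%, 4.38% and 4.40%. In the neutrophil progenitor-like simulation the initial unchanged list lay at percentile 99.7, so 160 unchanged lists per comparison were then simulated, of which 1.88%, 5.63% and 3.13% lay outside the random range. The simulated counts were Poisson draws from the same profile, the model behind the intervals. They held no spread between cells, no shared variation of list members and no shift of the median gene. The low rates for unchanged genes and lists were thus largely set by the design and do not calibrate the calls in the real data. Coordinates are from GENCODE M21 on the same build, in which all 153 gene identifiers looked up were found.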

Results

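The data describe c-Kit-sorted bone marrow cells of WT and Ints11-deleted mice. Ints11 is the endonuclease subunit of Integrator, a complex that cleaves nascent RNA at small nuclear RNA genes and at many promoters. Each genotype had 1 library of cells pooled from 2 mice, so there were no replicates. The WT matrix held 1.89e+08 UMIs, with a median of 18933 UMIs per barcode before filtering. The counts of the KO library were not analysed here, and every expression value below comes from the WT library.

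The comparison between genotypes was limited to the called barcodes. The KO library had 12170 called barcodes, 1.31 times the number in the WT library. Since the number of called barcodes depends on how many cells were loaded, this ratio measures no change in the marrow. The level of Ints11 in the KO, the usual check of a deletion, was not analysed here.

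The question for the WT library was which cell types a c-Kit sort held 4 days after poly(I:C). Cells of the neutrophil lineage made up most of it. Late neutrophil-like cells, with secondary granule genes among their markers, accounted for 3342 of 8018 cells (41.7%, interval 40.6 to 42.8), and neutrophil progenitor-like cells for 2388 (29.8%, 28.8 to 30.8). Monocyte lineage-like cells followed with 848 (10.6%, 9.91 to 11.3), lymphoid progenitor-like cells with 377 (4.70%, 4.25 to 5.19) and HSPC-like cells with 347 (4.33%, 3.89 to 4.80). Megakaryocyte lineage-like cells numbered 200 (2.49%), basophil or mast-like cells 170 (2.12%) and conventional dendritic-like cells 159 (1.98%). The smaller classes were T or NK-like (83 cells), erythroid progenitor-like (58) and macrophage-like (29), and a cluster of 17 cells led by immunoglobulin genes stayed unnamed. Late neutrophil markers summed to 440992 CPM in late neutrophil-like cells, to 80557 in neutrophil progenitor-like cells and to 4478 in HSPC-like cells. The 4 neutrophil progenitor-like clusters differed in this, from 0.48% of UMIs in a cluster of 506 cells to 24.8% in one of 657. The sum was 11178 CPM in megakaryocyte lineage-like, 11032 in conventional dendritic-like and 10830 in basophil or mast-like cells, above the HSPC-like level. Class shares moved with the filter and the resolution, the HSPC-like share reaching 6.45% with doublets kept. At resolution 0.5 none of the clusters was named HSPC-like, and 648 cells took the name eosinophil lineage-like, so names also depended on the settings.

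**Figure D1:**
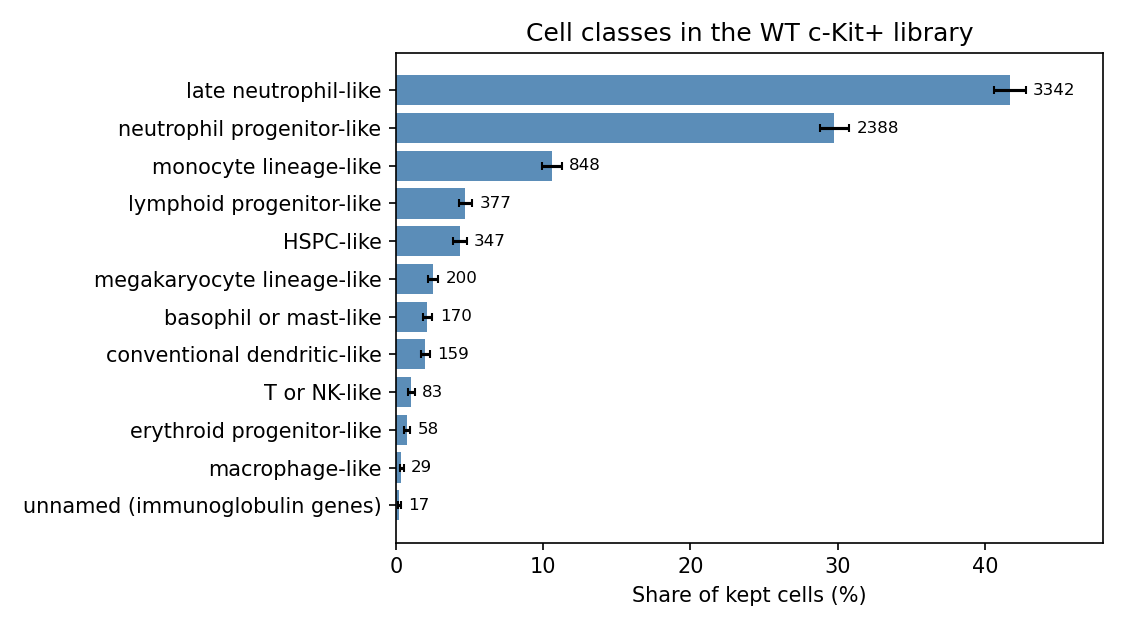
Share of the 8018 kept cells of the WT library in each cell class, in percent, with exact Clopper-Pearson 95% intervals as error bars and the number of cells beside each bar. Late neutrophil-like (3342 cells) and neutrophil progenitor-like cells (2388 cells) outnumbered the HSPC-like class (347 cells).

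Ints11 transcript was present in every named class at a narrow range of levels. Ints11 (ENSMUSG00000029034, mm10 chromosome 4, 155869546 to 155889103, plus strand, protein coding) stood at 58.0 CPM in HSPC-like cells (561 UMIs, interval 53.3 to 63.0). It was higher in monocyte lineage-like cells (65.9 CPM, ratio 1.14, 1.03 to 1.25) and in megakaryocyte lineage-like cells (67.9 CPM, ratio 1.17, 1.02 to 1.34), and both directions held relative to the median gene. In neutrophil progenitor-like cells Ints11 was at 55.3 CPM (ratio 0.955, 0.872 to 1.05), a log2 ratio of -0.07 that became 0.62 relative to the median gene. In late neutrophil-like cells Ints11 was lower in CPM (40.1 CPM, ratio 0.691, 0.630 to 0.760; log2 ratio -0.54), but the direction reversed to 0.72 under median gene scaling and to 0.26 when the most abundant genes were left out of the totals. The 50 most abundant genes took 58.3% of the UMIs in late neutrophil-like cells, 33.3% in neutrophil progenitor-like cells and 26.5% in HSPC-like cells, and the median gene was shifted by -1.26 and -0.69 in log2 in the former 2 classes, by -0.37 in monocyte lineage-like cells and by 0.02 in megakaryocyte lineage-like cells. Lymphoid progenitor-like (60.0 CPM), conventional dendritic-like (53.9) and basophil or mast-like cells (47.3) completed the classes of at least 100 cells. Pusl1 overlaps the 3' end of Ints11 on the other strand.

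Cpsf3, the paralog of Ints11 that cleaves pre-mRNA at poly(A) sites, was at 53.9 CPM in HSPC-like cells (ENSMUSG00000054309, chromosome 12, 21285391 to 21315056, plus strand). Its ratio was 0.983 (0.845 to 1.14) in megakaryocyte lineage-like and 0.905 (0.818 to 1.001) in monocyte lineage-like cells. In neutrophil progenitor-like cells Cpsf3 stood at 34.2 CPM (ratio 0.633, 0.574 to 0.699) and in late neutrophil-like cells at 19.0 CPM (ratio 0.352, 0.317 to 0.392). The former ratio was close to that of the median gene.

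Kit, the gene of the sorted receptor (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, plus strand), differed widely between classes. It was at 101 CPM in HSPC-like cells, 88.4 in megakaryocyte lineage-like, 79.1 in conventional dendritic-like, 75.2 in erythroid progenitor-like and 68.3 in basophil or mast-like cells. Kit was lower in neutrophil progenitor-like (31.7 CPM, ratio 0.313, 0.289 to 0.339), lymphoid progenitor-like (26.6, ratio 0.263) and monocyte lineage-like cells (23.9, ratio 0.237). In late neutrophil-like cells it was 7.80 CPM (423 UMIs, ratio 0.0772, 0.0687 to 0.0866). At 5000 UMIs per cell, 38.1% of HSPC-like cells had a Kit UMI (interval 32.9 to 43.4; 87.6% before thinning, median 26980 UMIs). The share was 3.27% in late neutrophil-like cells (2.68 to 3.93; before thinning the share was 11%, median 16362 UMIs). Macrophage-like cells, which should lack Kit, had 1 of 29 cells with a Kit UMI (3.45%, 0.0873 to 17.8; 6.90% before thinning, median 18801 UMIs). These cells were too few to set a background level for the late neutrophil-like share. Thinning left out 3 HSPC-like, 65 late neutrophil-like and 0 macrophage-like cells.

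**Figure D2:**
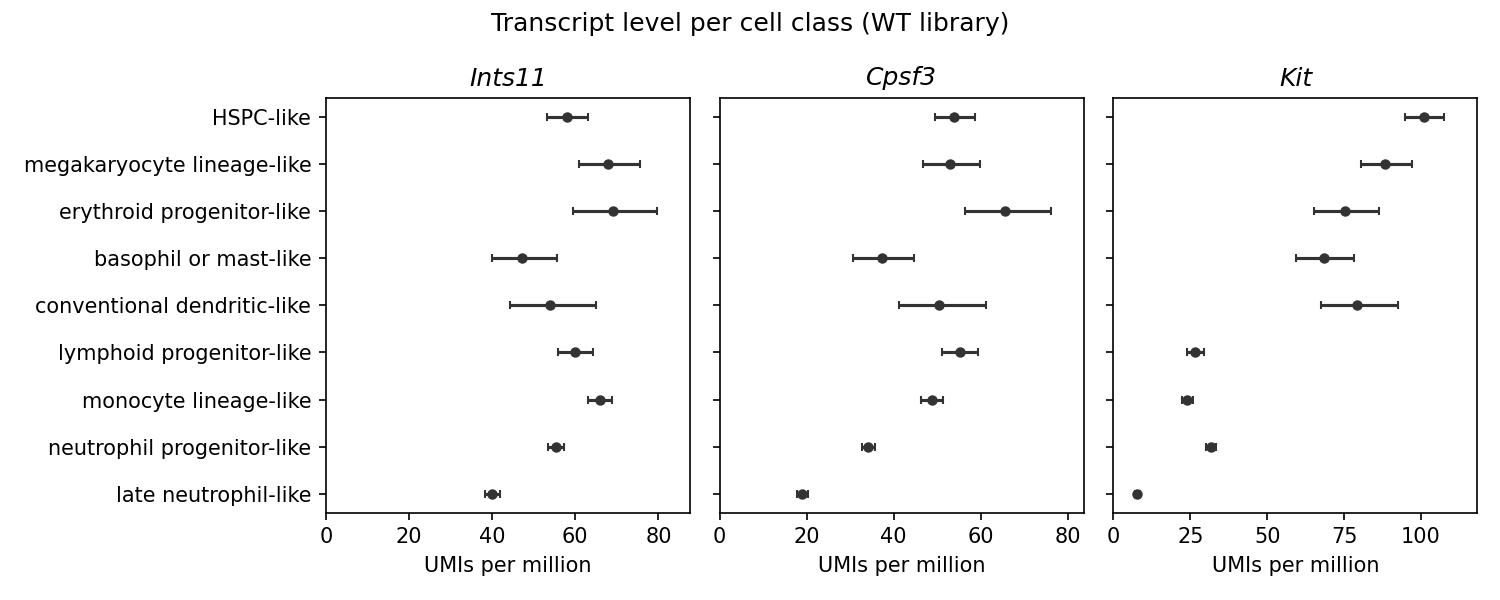
UMIs of Ints11, Cpsf3 and Kit, in CPM, in 9 cell classes of the WT library, as points with exact Poisson 95% intervals (horizontal axes, each starting at 0). Ints11 stayed between 40.1 in late neutrophil-like and 69.0 in erythroid progenitor-like cells, the lower late neutrophil-like value reversing its direction against HSPC-like cells under median gene scaling, while Kit ran from 7.80 to 101.

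The Integrator subunits as a list did not stand apart from matched random lists in any class of at least 100 cells. The median of the 14 subunits, relative to the median gene, was -0.24 in neutrophil progenitor-like cells (percentile 11.6), -0.13 in monocyte lineage-like (17.5), 0.05 in megakaryocyte lineage-like (57.3) and -0.19 in late neutrophil-like cells (20.2). In neutrophil progenitor-like cells 8 subunits were lower and 1, Ints12, was higher (18.3 against 12.0 CPM, log2 1.29 relative to the median gene). Ints4 (5.85 against 18.2 CPM, -0.95) and Ints1 (15.4 against 37.8 CPM, -0.60) were the lowest there. In monocyte lineage-like cells Ints11 and Ints12 were higher and 4 subunits lower, with Ints4 at -0.45 and Ints6 at -0.33. In megakaryocyte lineage-like cells Ints11 and Ints5 were higher (Ints5 23.7 against 15.9 CPM, log2 0.56), Ints2 was lower (-0.43), and 11 subunits passed neither criterion. Ints5 shares its locus with an overlapping annotated gene, so its count is less certain.

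Relative to the median gene, neutrophil progenitor-like cells held less RNA of interferon-response, immediate-early, ribosome biogenesis and Hox genes than HSPC-like cells, and more of heme synthesis and histone genes. In CPM, without the shift of the median gene, the list medians were 0.21 for heme synthesis and -0.09 for histones. The summed CPM of these 2 lists were at ratios of 2.33 and 1.38, with Alas1 holding 628 of the 865 CPM of the heme genes. Of the 15 lists besides Integrator, 7 lay outside the random range, among them p53 targets, whose call ended under 6 alternatives. Of 30 interferon-response genes 21 were lower and 0 higher, with a list median of -0.65 (percentile 0): the immune GTPase gene Iigp1 was at 0.877 against 23.7 CPM (log2 -4.04) and Ifit3 at 0.256 against 5.27 CPM (-3.60). Hoxa and Hoxb genes pattern the embryo and are active in early progenitors. Of these, 9 of 10 were lower, with a median of -2.14 (percentile 0.320), among them Hoxa10 (0.311 against 8.47 CPM, -4.01) and Hoxa7 (7.97 against 50.7 CPM, -1.98). Hoxa9, which is not in the list, was among the markers that named the HSPC-like class. Lower Hox genes, in this and other classes, are thus not independent of that naming. Heme synthesis genes had a median of 0.90 (percentile 99.95), led by Alas1, the rate-limiting enzyme of the pathway, at 628 against 102 CPM (ratio 6.15, 5.77 to 6.55; log2 3.31), while Alad was lower (17.2 against 54.6 CPM, -0.97). By members, 3 of 12 heme genes were higher, 1 lower and 8 neither.

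Among ribosome biogenesis genes 19 of 26 were lower, 0 higher, and the median was -0.32 (percentile 0), with the nucleolar gene Npm1 at 1476 against 3043 CPM (-0.35) and Polr1a, the largest subunit of RNA polymerase I, at 11.9 against 40.0 CPM (-1.05). Immediate-early genes, which respond within minutes to stimuli including cell handling, had 11 of 14 members lower and a median of -0.50 (percentile 0.460), with Egr1 at 0.950 against 19.8 CPM (-3.67) and Jun at 236 against 422 CPM (-0.15). The p53 target list had a median of -0.84 (percentile 2.18), with 8 of 14 lower, such as Phlda3 (-3.83), and Fas higher (5.06 against 1.86 CPM, 2.06). Replication-dependent histones had a median of 0.60 (percentile 100), with 18 of 61 higher, 4 lower and 39 neither. Hist1h1b, a linker histone gene, was at 725 against 299 CPM (1.97) and Hist3h2ba at 0.0914 against 7.13 CPM (-5.35). Under those 6 alternatives the p53 targets lay at percentiles 3.02 to 14.6, and the immediate-early call ended without the cell filter (3.07).

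The other 8 lists lay inside the random range in neutrophil progenitor-like cells under the main settings. Their medians were 0.40 for S phase (percentile 55.7), 0.50 for G2/M (92.7), 0.89 for oxidative phosphorylation (93.9), 0.15 for Myc and metabolism (6.30), -0.21 for cytokine receptors (10.6), -0.28 for PRC2 (5.98), -0.23 for cleavage and polyadenylation (2.72) and 0.03 for polymerase II pausing (17.1). Of these, 4 passed the range under some alternatives: Myc and metabolism under 3 (percentiles 0.64 to 1.57), G2/M under 2 (98.6 and 99.9), cleavage and polyadenylation under 2 (1.54 and 2.49) and PRC2 under 1 (1.99). Single members went further: Rrm2, a ribonucleotide reductase subunit, was at 334 against 101 CPM (2.42), Ndufb3 of respiratory complex I at 415 against 190 CPM (1.82) and the glycolytic gene Eno1 at 386 against 166 CPM (1.91). Among cytokine receptors the GM-CSF receptor subunit Csf2ra (151 against 39.3 CPM, 2.63) and the interferon gamma receptor Ifngr1 (362 against 107 CPM, 2.45) were higher and 9 members lower, such as Il6st (-2.97). Among genes outside the lists, markers and clustering genes the highest ratios were those of Hsd11b1, which interconverts active and inactive glucocorticoids (131 against 3.62 CPM, ratio 36.1, 25.9 to 51.9), Clec4a2 (ratio 26.1), coagulation factor X, F10 (20.1), Cldn15 (18.9) and Sgms2 (18.9). The lowest were those of Eng, endoglin (3.69 against 53.9 CPM, ratio 0.0684), Ssbp2 (0.124), Zfp608 (0.127), Ipo11 (0.144) and Krt18 (0.171).

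Megakaryocyte lineage-like cells differed from HSPC-like cells mainly in higher immediate-early, histone, heme synthesis, p53 target, G2/M and ribosome biogenesis genes and in lower cytokine receptor genes. Of the 15 lists 8 lay outside the random range. Immediate-early genes had a median of 1.06 (percentile 100) with 10 of 14 higher: the transcription factor gene Egr1 was at 203 against 19.8 CPM (ratio 10.3, 8.78 to 12.0; log2 3.33) and Jun at 1007 against 422 CPM (1.24), while Zfp36 was lower (-0.45). Cytokine receptors had a median of -1.12 (percentile 0) with 14 of 17 lower, including the G-CSF receptor Csf3r (3.41 against 49.8 CPM, -3.81) and Il6ra (2.81 against 17.3 CPM, -2.55), whereas the IL-33 receptor Il1rl1 was higher (25.9 against 1.65 CPM, 3.88). G2/M genes had a median of 0.34 (percentile 100) with 41 of 54 higher, 2 lower and 11 neither, such as the proliferation marker Mki67 at 441 against 192 CPM (1.18) and Ckap2l (1.32). Kif23, which acts in cytokinesis, was lower (32.9 against 49.4 CPM, -0.60), as was Ect2 (-0.62).

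Heme synthesis genes had a median of 0.56 (percentile 100) with 8 of 12 higher: Cpox was at 50.4 against 21.3 CPM (1.22) and Tspo2, an erythroid gene, at 96.4 CPM (480 UMIs) against 3 UMIs in HSPC-like cells (ratio 311, 106 to 1514). Alas1 was lower (30.7 against 102 CPM, -1.74). The class had 1 erythroid progenitor marker among its 10 leading genes, while haemoglobin genes held 0.00112% of its UMIs against 0.00651% in HSPC-like cells. Ribosome biogenesis genes had a median of 0.25 (percentile 99.99) with 21 of 26 higher, such as Rrp9 (67.9 against 39.1 CPM, 0.78), and p53 targets a median of 0.42 (percentile 99.8) with 8 of 14 higher and 2 lower, among them Btg2 (121 against 40.2 CPM, 1.57) and Pmaip1 (-1.58). Histones had a median of 0.60 (percentile 100) with 31 of 52 higher, for example Hist1h2ap (697 against 478 CPM, 0.53). The interferon-response list was lower in the median (-0.18, percentile 0.660), but its members went both ways: 7 were higher, such as Usp18 (45.8 against 17.5 CPM, 1.37) and Ifit1 (1.01), 11 were lower, such as Ifi44 (-0.88), and 12 were neither.

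Inside the random range in megakaryocyte lineage-like cells were S phase (0.01, percentile 22.6), oxidative phosphorylation (-0.08, 2.77), Myc and metabolism (-0.05, 14.9), Hoxa and Hoxb (-0.44, 16.5), PRC2 (-0.09, 16.8), polymerase II pausing (0.02, 38.7) and cleavage and polyadenylation (0.03, 46.7). Mycn was higher (31.3 against 6.10 CPM, 2.33) and the glycolytic gene Pkm lower (261 against 548 CPM, -1.09). Among genes outside the lists, markers and clustering genes the autophagy receptor gene Optn (61.5 against 1.65 CPM, ratio 37.2, 22.5 to 65.9), Tuba8 (15.3), Tgfbr3 (50.4 against 6.30 CPM), Hemgn (5.26) and Ehd3 (3.87) had the highest ratios. Plppr3 (0.0246), Kcnk12 (0.0410), Cd53 (0.0438), Hk3 (0.0691) and Milr1 (0.0724) had the lowest. Under 4 alternatives these cells joined the erythroid progenitor-like cells in a cluster of 257 to 297 cells and gave no value of their own. The interferon-response call ended with doublets kept (percentile 28.7), and oxidative phosphorylation passed the range under 3 alternatives (0.24 to 2.19).

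Relative to the median gene, monocyte lineage-like cells had less RNA of interferon-response, immediate-early and Hox genes than HSPC-like cells and more of histone genes. In CPM, without the shift of the median gene, the histone list median was -0.01, while the histone sum was at a ratio of 1.31. Of the 15 lists 5 lay outside the random range. Interferon-response genes had a median of -0.72 (percentile 0) with 25 of 30 lower and 0 higher, such as Rsad2, viperin (2.46 against 22.4 CPM, -2.81), and Ifit3 (-2.67). Immediate-early genes had a median of -0.73 (percentile 0) with 9 of 14 lower, Egr1 at 1.24 against 19.8 CPM (-3.60) among them, while the heat-shock genes Hspa1a (23.0 against 5.58 CPM, 2.38) and Hspa1b (2.09) were the 2 that were higher. Hoxa and Hoxb genes had a median of -2.24 (percentile 0.0300) with 9 of 10 lower, and Hoxa10 held 3 UMIs (ratio 0.0116, 0.00234 to 0.0351). Histones had a median of 0.36 (percentile 100) with 18 of 59 higher and 6 lower, Hist1h1b at 712 against 299 CPM (1.62).

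Ribosome biogenesis genes in monocyte lineage-like cells had a median of 0.04 relative to the median gene but lay below random lists of like expression (percentile 0.420), with 5 of 26 members lower, 3 higher and 18 neither. Polr1a was at 24.3 against 40.0 CPM (-0.35) and Nhp2 at 425 against 313 CPM (0.81). That call ended with doublets kept (percentile 4.57). Without the cell filter the median turned to -0.02 and the list still lay below random lists (percentile 0.04).

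Oxidative phosphorylation genes in monocyte lineage-like cells had 20 of 21 members higher, such as cytochrome c, Cycs, at 609 against 257 CPM (ratio 2.37, 2.27 to 2.47; log2 1.61), yet the list median of 0.72 stayed within the random range (percentile 96.3). It passed that range under 5 alternatives (percentiles 98.2 to 99.4). Heme synthesis was at 0.27 (percentile 91.3) with Alas1 at 360 against 102 CPM (2.18), Myc and metabolism at 0.48 (80.5) with Eno1 at 365 against 166 CPM (1.51) and Myc itself at 56.0 against 167 CPM (-1.21). S phase was at 0.33 (56.7), G2/M at 0.13 (4.11), cytokine receptors at 0.17 (70.4), p53 targets at -0.22 (34.2), PRC2 at -0.10 (10.6), polymerase II pausing at 0.18 (46.4) and cleavage and polyadenylation at -0.04 (11.6). G2/M passed the range under 4 alternatives (0.08 to 1.83) and heme synthesis with doublets kept (99.1). Among genes outside the lists, markers and clustering genes the Fc gamma receptor gene Fcgr3 (190 against 17.5 CPM, ratio 10.9, 9.34 to 12.8), Clec5a (7.55), Cldn15 (7.22), Gda (6.14) and C1galt1c1 (6.02) were highest, and Fam69b (0.0883), the fatty acid receptor gene Ffar2 (0.159), Krt18 (0.172), Zfp608 (0.194) and Rps6ka3 (0.213) lowest.

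**Figure D3:**
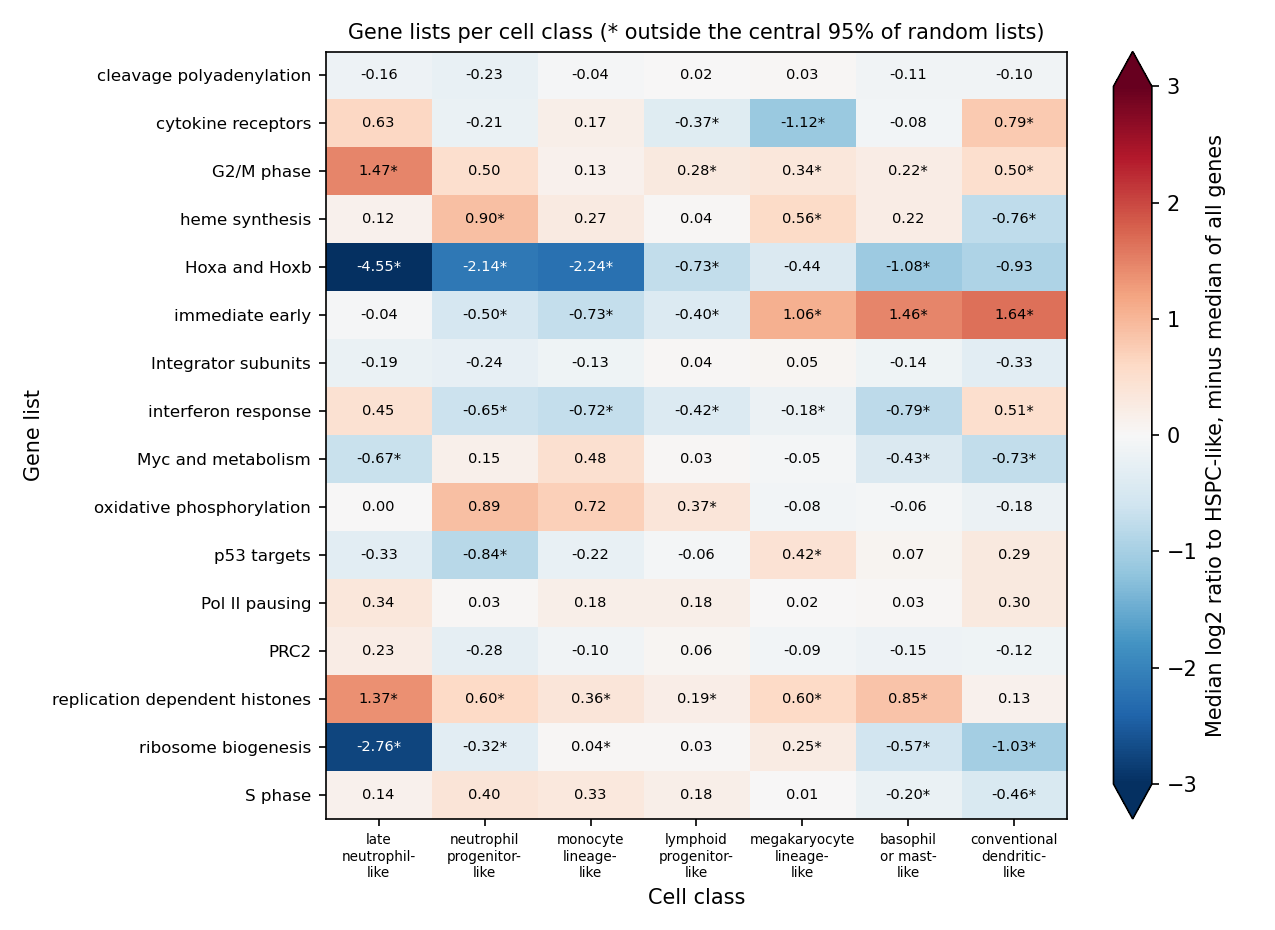
Median log2 ratio of each of 16 gene lists to the HSPC-like class, minus the median of all tested genes, in 7 cell classes of the WT library (colour and printed value; the colour scale ends at 3 in either direction). An asterisk marks a median outside the central 95% of 10000 matched random lists, which was the case for 48 of 105 comparisons besides Integrator and for none of the Integrator list.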

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

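The tests in this part were all chosen only after the result was seen. A total of 35 barcodes occurred in both the WT and the KO barcode list (Poisson interval 24.4 to 48.7), an overlap that no comparison of the report addressed. Reads carried from KO cells into the WT library would leave mostly shallow barcodes. However, 1 of the 35 held under 2000 UMIs, against 5.61% of all WT barcodes, and their median was 18097 UMIs. The data thus argue against this source for most of the 35. Only barcodes that had passed cell calling were listed, so carried reads in shallower barcodes could not be seen. Reads carried from WT cells into the KO library cannot be told apart from other sources: the shared barcodes had a median depth percentile of 45.7 in the WT library, inside the 34.0 to 66.1 of random draws, and the KO counts were not analysed here. Chance reuse gives 16.7 shared barcodes if both libraries drew evenly from the barcode list assumed for the kit, fewer than seen, yet uneven use of that list could raise the number, so it also stays open. No biological explanation was tested, and 29 of the 35 barcodes were among the cells kept and so entered the clustering.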

How the results depend on the processing

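Random lists without clustering genes and the comparison of Ints11 with the other subunits were chosen only after the results were seen. The cells kept ran from 6952 to 8984. Without the cell filter the shares were 5.77% HSPC-like, 24.5% neutrophil progenitor-like, 9.80% monocyte lineage-like and 38.4% late neutrophil-like, and with the stricter filter 4.99% HSPC-like, 34.6% neutrophil progenitor-like and 35.3% late neutrophil-like. With doublets kept they were 6.45% HSPC-like, 28.3% neutrophil progenitor-like and 11.4% monocyte lineage-like. At resolution 0.5 neutrophil progenitor-like cells made up 27.2% and monocyte lineage-like cells 14.9%, and at resolution 2.0 they made up 32.2% and 13.3%, with 36.8% late neutrophil-like. With 4000 variable genes the HSPC-like share was 4.84% and the monocyte lineage-like share 13.5%. The latter was 11.7% with clusters and values from separate UMIs, and the neutrophil progenitor-like share was 30.8% with list genes allowed in clustering. For these shifts the cause was not tested. The Ints11 log2 ratio became 0.62 in neutrophil progenitor-like, 0.55 in monocyte lineage-like and, reversed, 0.72 in late neutrophil-like cells under median gene scaling. It became 0.10 and, reversed, 0.26 in the neutrophil progenitor-like and late neutrophil-like classes without the most abundant genes, as a scaling shifts every gene of a class alike. The ribosome biogenesis median in monocyte lineage-like cells changed sign to -0.024 without the cell filter, and the cause was not tested. The list stayed below random lists there (percentile 0.04), so its call was kept. The Integrator list stayed inside the random range in each alternative that gave a value, but its median changed sign over them in 3 classes, running from -0.295 to 0.010 in neutrophil progenitor-like, from -0.133 to 0.080 in monocyte lineage-like and from -0.244 to 0.038 in late neutrophil-like cells, and the cause was not tested. The other lists outside that range numbered 6 to 9 in neutrophil progenitor-like, 8 to 9 in megakaryocyte lineage-like and 5 to 7 in monocyte lineage-like cells. Over lists and alternatives 464 values were the same, 19 moved past the random range, 9 moved inside it and 2 changed sign and moved past it (Myc and metabolism in neutrophil progenitor-like cells). A further 1 changed sign but kept its call (ribosome biogenesis in monocyte lineage-like cells). For the genes named outside the lists 175 values stayed within counting error, 95 moved and 0 reversed; for Ints11 against the other subunits 33 stayed and 4 moved. At resolution 0.5 no cluster was named HSPC-like, so ratios had no value, and 648 cells were named eosinophil lineage-like. Plasma cell-like cells numbered 323 with the stricter filter and 134 with 4000 variable genes. Neither name was given under the main settings. Without the cell filter 825 cells stayed unnamed, so the class names themselves depended on the settings. Megakaryocyte lineage-like cells had no value under 4 alternatives. No split by sex of the pooled mice could be made (3 Y-linked UMIs). No paired analysis was possible because each genotype had 1 library and no replicate numbers. Depth limits the smaller classes: 71% of 1.5-fold simulated changes were recovered for megakaryocyte lineage-like cells.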

Other observations

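The tests of depth, of granule transcripts and of free RNA by single abundant markers for Kit were chosen only after the result was seen. Late neutrophil-like cells, the most numerous class, had more RNA of G2/M genes than HSPC-like cells relative to the median gene (list median 1.47, percentile 100, 32 of 54 higher, 2 lower and 20 neither) and of histone genes (1.37, percentile 100, 22 of 59 higher, 5 lower and 32 neither). In CPM, without the shift of the median gene, these list medians were 0.22 and 0.11. The class had less of ribosome biogenesis (-2.76, percentile 0, 26 of 26 lower), of Hoxa and Hoxb (-4.55, percentile 0.075) and of Myc and metabolism genes (-0.67, percentile 1.22, 9 of 17 lower, 3 higher and 5 neither), while S phase genes stayed inside the random range (0.14, percentile 21.7). The G2/M genes were unevenly spread over the class. Their sum was 15396 CPM in a cluster of 716 cells whose S phase genes summed to 1565 CPM, and 2365 CPM in a cluster of 304 cells whose S phase genes summed to 285 CPM. In HSPC-like cells the sums were 6793 and 4095 CPM.

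The smaller classes differed from HSPC-like cells in several of the same lists. All ratios of all classes share the 347 HSPC-like cells as reference. Calls that recur across classes are therefore not independent, and a level particular to the reference would move them all. By list medians, immediate-early genes were higher in basophil or mast-like (1.46, percentile 100, 9 of 14 higher and 2 lower) and conventional dendritic-like cells (1.64, percentile 100, 13 of 14 higher) and lower in lymphoid progenitor-like cells (-0.40, percentile 0.010, 8 of 14 lower and 3 higher). The interferon-response median was lower in basophil or mast-like (-0.79, percentile 0, 18 of 30 lower and 2 higher) and lymphoid progenitor-like cells (-0.42, percentile 0, 16 of 30 lower and 4 higher). Their summed interferon-response RNA was not lower, at ratios of 1.012 (0.987 to 1.037) and 1.003 (0.987 to 1.019). In conventional dendritic-like cells these genes were higher (0.51, percentile 98.9, 14 of 30 higher and 7 lower). Ribosome biogenesis genes were lower in conventional dendritic-like (-1.03, percentile 0, 25 of 26) and basophil or mast-like cells (-0.57, percentile 0, 20 of 26). Oxidative phosphorylation genes were higher in lymphoid progenitor-like cells (0.37, percentile 99.99, 18 of 21). Cytokine receptor genes were higher in conventional dendritic-like cells (0.79, percentile 99.6, 8 of 16 higher and 2 lower). In lymphoid progenitor-like cells their median was lower (-0.37, percentile 0), but members went both ways, with 7 of 17 higher and 8 lower, and their sum was at a ratio of 0.975 (0.943 to 1.007). The lymphoid progenitor-like class had no named counterpart under 3 alternatives. Its 10 leading genes held 2 of its own markers and 2 of plasmacytoid dendritic cells, Cox6a2 and Tcf4. Its values may therefore not be those of lymphoid progenitors alone. The basophil or mast-like class had 2 eosinophil markers among its 10 leading genes, and with doublets kept and at resolution 2.0 a cluster of 25 eosinophil lineage-like cells stood apart from 137 and 138 basophil or mast-like cells, so its values are those of a mixed class.

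Kit transcript was low in late neutrophil-like cells although the cells had been sorted for c-Kit protein. Lower depth alone is argued against, since 3.27% of these cells had a Kit UMI at equal depth, below the HSPC-like interval of 32.9 to 43.4, and so is a loss of counts to granule transcripts, since Kit was at -2.44 in log2 (-2.61 to -2.27) relative to the median gene. Both values follow largely from the Kit CPM and the shift of the median gene given above, so they are no independent evidence. The free-RNA test written first, when the low Kit was known, gave a smallest ratio of 0.276 but is void, because some of its markers, such as Hdc at 154% of the library mean, were not foreign to these cells. It was replaced once that value was seen. Against the most abundant marker of each of 3 lineages the smallest ratio was 4.23 (Pf4, 3.37 to 5.35). Over the class as a whole this is more Kit than those markers predict from free RNA alone. Kit was uneven within the class, however. It was at 2.78 CPM (1.67 to 4.33) in a cluster of 523 cells and 2.34 (1.01 to 4.62) in one of 304. In a cluster of 716 cells it was at 8.65 CPM. The comparison was not made per cluster, so free RNA stays open for the clusters with low Kit. Kit in macrophage-like cells, at 5.71 CPM (1.18 to 16.7, 3 UMIs), was too sparse to set a background below the 7.80 CPM of late neutrophil-like cells. Protein that outlasts its transcript, or cells passing the sort gate without c-Kit, could each give this pattern, and neither nor any other biological explanation was tested.

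Ints11 was high against the other Integrator subunits in neutrophil progenitor-like cells, by 0.87 in log2 (0.70 to 1.04) over the median of 13 others. This difference is unaltered by a scaling that shifts every gene of a class alike. It was 0.67 to 0.97 over the alternatives. The difference was 0.92 in late neutrophil-like (0.72 to 1.01 over the alternatives), 0.68 in monocyte lineage-like (0.32 to 0.74) and 0.17 in megakaryocyte lineage-like cells (counting interval -0.07 to 0.40). Ints11 was not the subunit that stood furthest out, since the log2 ratio to HSPC-like cells was 0.60 for Ints12 against -0.07 for Ints11 in neutrophil progenitor-like cells and 1.68 against -0.54 in late neutrophil-like cells. Transcript length as the whole cause is argued against, as 0.80 (0.57 to 0.95) remained after removal of a trend in which genes with transcripts under 1500 bases had a median log2 ratio of -0.39 and those over 4000 bases of -1.01. Reads of the overlapping gene Pusl1 remain open: it held 269 UMIs where 1374 would be needed. Molecules of Pusl1 miscounted as Ints11 would be missing from that number, so it cannot decide the question. No biological explanation was tested, and other technical sources such as the choice of poly(A) site were not examined.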
